A study of Mus musculus with 12 samples.

How the data were processed

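RNA was measured in 12 libraries of RAW264.7 cells, a mouse macrophage line. Per the labels' protocols, total RNA was taken with a column kit from clones with a CRISPR deletion named NRE1 (KO) and from wild-type clones (WT), kept in medium or given LPS at 10 ng/mL with IFN-gamma at 50 ng/mL for 6 h. LPS is a bacterial cell wall component sensed by Toll-like receptor 4, and interferon gamma is a lymphocyte cytokine; together they drive macrophages toward an inflammatory state. The labels call the samples clones (WT 1, 2 and 3, KO 1A, 1B and 2), each with 1 library per condition, so the 4 groups hold 3 libraries each. P-values of the primary fit measure the spread between clones within groups, pooled over the 4 groups. They do not measure how the responses vary between clones. If KO 1A and 1B stem from 1 clone, the KO groups hold 2 independent clones. The labels do not expand the name NRE1 or say how clones 1A and 1B are related, and no gene in the table bears that name, so no targeted gene could be read in each library.

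The authors deposited 1 table of gene counts for all libraries, as whole numbers per Ensembl gene. The read aligner, the counting tool and whether counting used strand are not given in the sources used here. The genome build was mm10 (GRCm38), per the submitters' processing notes, which also name DESeq2 without its version or role. The deposited table listed 12483 genes, each with at least 5 counts in its second-highest library, and 66 of its counts were written in exponent form. Gene names, positions and biotypes came from GENCODE release M21 of the same build, which named 12305 of the IDs and left 178 without a name. In 12 genes the counts equalled those of another gene in every library, and genes sharing exons with an overlapping gene over at least 30% of their length were marked as uncertain.

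Total counts per library ran from 10624591 to 14388590. Intervals on folds of genes with 3 or fewer counts in a group are 95% counting intervals, and a group with 0 counts was given a floor of 3 counts over the group, which makes the fold a lower bound. Such intervals and floors cover counting error only. Levels are CPM (counts scaled to a common library size) computed from TMM-scaled library sizes, given as mean ± SD over 3 libraries.

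Differential expression used edgeR 4.0.16 in R 4.3.3: filterByExpr kept 12231 genes and left out 252, TMM factors scaled the libraries, and robust quasi-likelihood fits with 1 mean per group over all 12 libraries left 8 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, with no fold threshold. The 5 comparisons were LPS/IFN-gamma against medium within WT clones and within KO clones, KO against WT in medium and under LPS/IFN-gamma, and the difference between the KO and the WT response (the interaction). Log2 fold changes are given ± SE, the fold change divided by the square root of its quasi-likelihood F. The common coefficient of variation between clones was 23.6%.

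The labels give each clone 1 library in each condition, which pairs the libraries by clone for the 2 responses and the interaction. The deviations of a clone's medium and stimulated libraries from their group means correlated at 0.64, 0.70 and 0.62 for WT 1, 2 and 3 and at 0.32, 0.29 and 0.51 for KO 1A, 1B and 2. Each medium library matched the stimulated library of its own clone best within its genotype. The highest correlation with another clone was 0.27 for KO 1A and 0.18 for KO 1B, and negative for the other clones. The fit with clone as a block left 4 residual degrees of freedom and a coefficient of variation of 11.7%. It was fixed as the alternative, not the primary fit, and is given beside a result where it changes the call.

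Gene groups came from 35 lists of 678 genes, of which 537 were measured. Lists with at least 5 measured genes were tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated for each list, and with fry, which asks whether the genes of a list move on balance 1 way. The 35 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each comparison of groups, the 8 highest and 8 lowest fold changes among called protein-coding genes with at least 5 CPM in 1 group and no overlap between the groups. It added up to 3 genes of each list with the smallest p, the 8 highest and 8 lowest genes called in both KO comparisons, 5 genes at each end of the interaction, and Nos2, Tnf, Il6, Il1b, Cxcl10 and Arg1 for the responses. For a gene named in 1 response, the value in the other is given for some genes only. Nampt and Kdm6a under stimulation, Gm47283, the X-linked partners of Y-linked genes, the neighbours of Gdap10, genes called only with the clone block and genes of NAD and itaconate metabolism were chosen after their values were seen.

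Alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, limma voom, no count filter and a stricter one, libraries thinned to the smallest total, a test against a fold of 1.5, only the libraries compared, the clone block, summed counts of KO 1A and 1B, and each clone left out. A voom fit with spread by genotype was added after the data were seen.

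The tests were tried on simulated counts with known changed genes. For KO against WT in medium, edgeR recovered 16.4%, 46.3% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold, and 5.56% of its 108 calls were false. These counts were drawn with no clone shared between the conditions, unlike the data. In no simulation were KO 1A and 1B drawn closer than other clones, or spreads set apart by genotype. All such shares therefore hold for the simulated settings only. For the WT response without a block, and with clones not shared between the conditions, the shares were 17.9%, 40.3% and 84.8%, with 9.52% of 105 calls false. For the interaction, counts were simulated with clones shared between the conditions. Without the block the shares were 0%, 10.4% and 65.2%, with 0 false among 50 calls, and with it 11.9%, 55.2% and 89.4%, with 11.9% of 118 calls false. For the WT response with clones shared they were 5.97%, 38.8% and 83.3% without the block, with 0 false among 85 calls, and 40.3%, 71.6% and 92.4% with it, with 8.72% of 149 calls false. DESeq2 recovered more genes, and 22.4% of its 156 calls for KO against WT in medium were false.

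Some results for single genes are not reported here.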

Results

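Transcript levels were measured in clones of the RAW264.7 mouse macrophage line with and without a deletion named NRE1, in medium and after LPS and IFN-gamma for 6 h. The 4 groups held 3 libraries each, and total counts per library ran from 10624591 to 14388590. The mitochondrial share of counts lay between 1.24% and 2.53%. The first principal component held 67.9% of the variance and parted stimulated from unstimulated libraries, and the next held 13.5%. KO clones 1A and 1B were closer to each other than any other pair. Their coefficient of variation was 6.0% in medium and 4.97% under stimulation, against 15.8% to 18.4% for their pairs with KO 2 and 23.8% to 33.1% between WT clones. Their counts differed by more than sampling noise (chi-square per degree of freedom of 6.76 in medium and 4.85 under stimulation), so they are not copies of 1 library, though cultures of 1 clone would differ in this way too. They were kept as separate clones because the labels name them so, and whether they stem from 1 clone was not tested. Counts with the 2 summed are given with each KO against WT comparison.

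**Figure D1:**
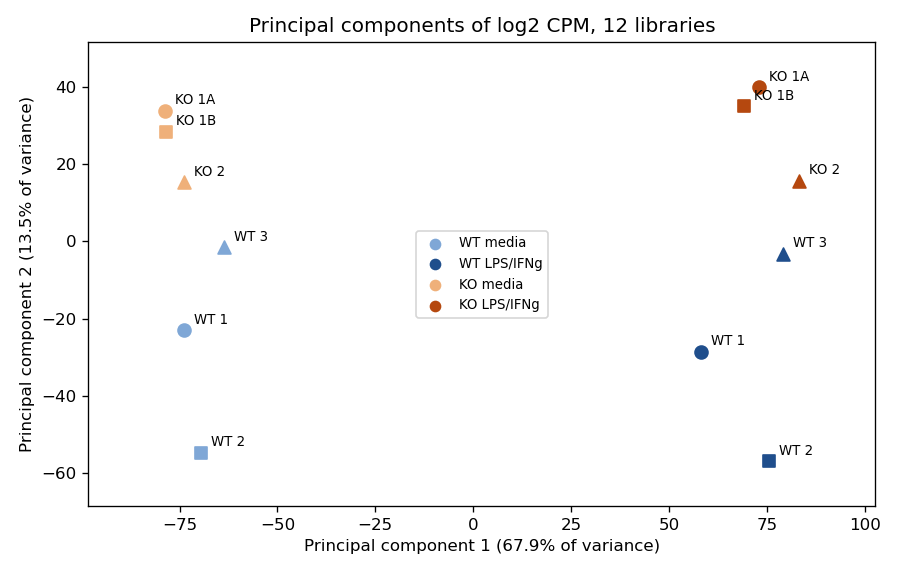
Principal components 1 and 2 of log2 CPM for the 12 libraries, in the units of the component scores, with color for the group and a label for the clone. Component 1 (67.9% of variance) parts the stimulated from the unstimulated libraries, and KO 1A and KO 1B lie next to each other in both conditions.

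In WT clones, LPS/IFN-gamma raised the classical inflammatory genes. Nos2, the inducible nitric oxide synthase, rose from 0.506 ± 0.170 to 839 ± 347 CPM (log2 fold change 10.70 ± 0.48, adjusted p = 1.3e-07). The interferon-inducible GTPases Iigp1 and Gbp2 rose by 11.36 ± 0.25 and 10.37 ± 0.32 on the log2 scale, to 2280 ± 353 and 2126 ± 216 CPM. The cytokine gene Tnf rose by 3.83 ± 0.19 to 1528 ± 177 CPM, Il1b by 10.78 ± 1.09, and the chemokine gene Cxcl10 by 5.73 ± 0.54 from 12.7 ± 4.23 CPM. In the other direction Csf1r, the receptor for the macrophage growth factor CSF1, fell from 2117 ± 527 to 588 ± 184 CPM (-1.85 ± 0.24, adjusted p = 0.00013).

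Of 12231 genes tested, 5796 were called in WT clones, 2913 higher and 2883 lower, and 652 of the higher and 362 of the lower ones passed a 4-fold change. Scaled by library totals alone, the median of all genes moved to -0.37 and 23.2% of the calls were higher, against 50.3% with TMM factors. The directions of the groups called by camera held under that scaling. A test against a fold of 1.5 called 2462 genes.

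Among the NF-kB targets, 28 of 29 measured genes rose and 1 was not called (29 higher adjusted over the list alone). They included the cytokine genes Il1a (10.25 ± 1.08) and Il6, whose counts of 1473 against 2 gave a 1002-fold ratio with a counting interval of 277 to 8280. Camera gave the NF-kB list an adjusted p of 1.1e-33, and adjusted p = 0.018 with an estimated correlation. All 25 genes of the IFN-gamma and GBP/IRG list rose (25 adjusted over the list alone, adjusted p = 9.5e-05 with an estimated correlation). Of 16 chemokine genes 15 rose, the same number adjusted over the list alone, among them Ccl22 (10.37 ± 0.51) and Ccl5 (8.82 ± 0.54), with adjusted p = 0.029 with an estimated correlation. Feedback inhibitors moved mostly upward, 19 of 24 higher and 2 lower under both adjustments, at adjusted p = 0.034 with an estimated correlation. Examples were Socs1 (6.59 ± 0.36), Socs3 (5.58 ± 0.31) and Nfkbia (2.13 ± 0.10), the gene of an NF-kB inhibitor.

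Type I interferon-stimulated genes rose in 32 of 34 cases (34 adjusted over the list alone), with Ifi204 at 6.65 ± 0.50, Oasl1 at 5.04 ± 0.46 and Stat2 at 3.96 ± 0.24. The call of that list was lost at adjusted p = 0.44 with an estimated correlation. MHC class I presentation genes rose in 17 of 18 cases (18 adjusted over the list alone). Among them were the peptide transporter gene Tap1 (4.36 ± 0.24), the class I regulator Nlrc5 (3.56 ± 0.15) and Tapbp (2.25 ± 0.14). Camera gave this list 9.5e-20, and adjusted p = 0.057 with an estimated correlation (0.016 with clone as a block). Glycolysis and hypoxia genes rose in 16 of 23 cases and fell in 1 (17 and 1 adjusted over the list alone), with the glucose transporter gene Slc2a1 at 2.30 ± 0.22. Camera gave 0.0024, and adjusted p = 0.44 with an estimated correlation, and under library totals 9 rose and 2 fell. Stress response genes, which serve amino acid shortage and protein folding in the endoplasmic reticulum, rose in 11 of 21 cases and fell in 1 (12 and 2 adjusted over the list alone). They included Herpud1 (1.13 ± 0.12) and Asns (0.81 ± 0.13), and camera gave 0.0027, and adjusted p = 0.44 with an estimated correlation.

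Genes of DNA replication and division fell. Of 30 proliferation genes 23 were lower and 7 not called (26 lower adjusted over the list alone). The helicase gene Mcm6 (-2.17 ± 0.36) and E2f1 (-1.83 ± 0.20) were among them. Camera gave 1.2e-06, and adjusted p = 0.51 with an estimated correlation. Replication-dependent histone genes were lower in 12 of 13 cases (13 adjusted over the list alone), with Hist1h1d at -2.50 ± 0.20, camera adjusted p = 9.7e-10 and adjusted p = 0.25 with an estimated correlation. Single genes far down were Fndc10 (-4.76 ± 0.47), Smad3 (-4.33 ± 0.27), the Ras inhibitor gene Rasa3 (-4.27 ± 0.42), the myeloid regulator Cebpa (-2.47 ± 0.33), and the lysosome regulator Tfeb (-2.30 ± 0.20). The chemokine receptor gene Cxcr4 had 400 counts in medium and 1 under stimulation, a 294-fold ratio with an interval of 52.5 to 11643, and its call was lost without WT clone 2 (adjusted p = 0.12).

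Smaller shifts were called by camera for 5 further lists, each lost with an estimated correlation. Toll-like receptor and interferon signalling components had 17 of 33 higher and 5 lower (adjusted p = 0.0039, and adjusted p = 0.44 with an estimated correlation). AP-1 and early response genes had 10 of 16 higher and 2 lower (0.0039, and adjusted p = 0.44 with an estimated correlation). Heat shock chaperones had 9 of 11 higher (0.016, and adjusted p = 0.44 with an estimated correlation). Phagocytosis and Fc receptor genes had 12 of 24 higher (0.016, and adjusted p = 0.57 with an estimated correlation). Extracellular matrix, adhesion and migration genes had 11 of 23 higher and 2 lower (0.021, and adjusted p = 0.49 with an estimated correlation). Each of these counts was the same adjusted over the list alone. Under library totals the higher and lower genes numbered 12 and 9 for signalling components, 9 and 2 for AP-1, 2 and 0 for chaperones, 8 and 0 for phagocytosis and 10 and 3 for matrix genes.

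The remaining lists were not called in WT clones. Higher and lower genes numbered 3 and 0 of 5 for MHC class II, 3 and 0 of 8 for alternative activation, 11 and 6 of 23 for macrophage identity, 4 and 3 of 15 for osteoclast genes and 5 and 7 of 19 for p53 targets. They numbered 4 and 1 of 15 for NRF2 targets, 3 and 5 of 22 for cholesterol synthesis, 3 and 1 of 15 for LXR targets, 7 and 0 of 27 for oxidative phosphorylation, 7 and 2 of 25 for lysosome genes and 0 of 7 for mitochondrially encoded genes. Adjusted over the list alone, MHC class II had 4 higher, oxidative phosphorylation 5 and lysosome genes 5, and the other counts stayed. The p53 list had a median of -0.12 and a mean of 0.12, with a camera test downward, and the cholesterol list a median of 0.03 and a mean of -0.13, also tested downward. Library totals turned the medians of the NRF2, cholesterol, oxidative phosphorylation and lysosome lists below 0, with 4 and 3, 1 and 6, 1 and 8, and 4 and 4 genes higher and lower. They gave 6 and 7 for macrophage identity, 4 and 9 for p53 targets and 3 and 3 for LXR targets. Arg1, an alternative activation gene, stood at 0.223 ± 0.218 CPM in medium and 0.889 ± 0.80 under stimulation (adjusted p = 0.23, and 0.024 with clone as a block).

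Markers of other cell types were sparse. None of the neutrophil, fibroblast and epithelial markers was measured. For B cells 1 marker was measured (Blnk, -0.86 ± 1.26, adjusted p = 0.605, and 0.0045 with clone as a block in WT and -2.01 ± 1.48, 0.27 and 0.00043 in KO clones). Also 1 marker each was measured for T or NK cells (Lck, 2.36 ± 0.42, adjusted p = 0.0011) and for mast cells (Kit, called higher in both genotypes). Dendritic cell markers had 3 of 6 higher in each genotype, with camera adjusted p = 0.068 in WT clones (0.010 with clone as a block, lost at adjusted p = 0.13 with an estimated correlation) and 0.13 in KO clones (0.020 with clone as a block, lost at adjusted p = 0.15 with an estimated correlation). Of 3 Notch genes 2 rose in each genotype, with Notch1 at 6.96 ± 0.49 in WT clones, and all 4 measured microRNA and host genes rose in each, with Mir155hg at 5.72 ± 0.29 in WT clones.

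In KO clones inflammatory genes rose as well. Nos2 rose from 0.415 ± 0.112 to 962 ± 237 CPM (11.12 ± 0.49, adjusted p = 1.0e-07). Tnf rose by 4.08 ± 0.19, Il1b by 10.63 ± 1.10 and Cxcl10 by 7.39 ± 0.59 to 1177 ± 80.0 CPM. Gbp2 rose by 10.33 ± 0.32 and Iigp1 by 10.08 ± 0.24 to 1295 ± 51.7 CPM. Il1a rose by 11.38 ± 1.14 and the cytokine gene Il27 by 11.20 ± 0.74. Csf1r fell by 2.40 ± 0.24 on the log2 scale, Cebpa by 3.29 ± 0.35 and Hist1h1d by 3.04 ± 0.20. In all, 6638 genes were called, 3260 higher and 3378 lower. A fold of 1.5 or more was called for 3198. Under library totals alone the median of all genes was -0.39 and 24.5% of the calls were higher, against 49.1% with TMM factors. Of the calls in the 2 genotypes, 2632 were higher in both, 2582 lower in both and 2 opposite, where independent lists would share 776 and 796. No library was common to these 2 comparisons.

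Several genes of the KO response had almost no counts in medium. The costimulatory ligand gene Cd86 had 0 counts in medium and 911 under stimulation, at least 420-fold higher against a floor of 3 counts over the group. Csf3, the gene of a granulocyte growth factor, had 6303 counts against 2 in KO clones (4357-fold, 1206 to 35986) and 3695 against 1 in WT clones (5026-fold, 902 to 198581). Ccl22 had 10983 against 3 in KO clones (5061-fold, 1732 to 24547), and Il6 3072 against 1 (4247-fold, 762 to 167808). Edn1, the endothelin-1 gene, was at least 356-fold higher under stimulation in WT clones, from 0 counts in medium, and 163-fold in KO clones, with an interval of 28.7 to 6498. Arg1 had 13 counts under stimulation and 2 in medium (8.99-fold, 2.03 to 82.0, adjusted p = 0.19, and 0.029 with clone as a block).

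**Figure D2:**
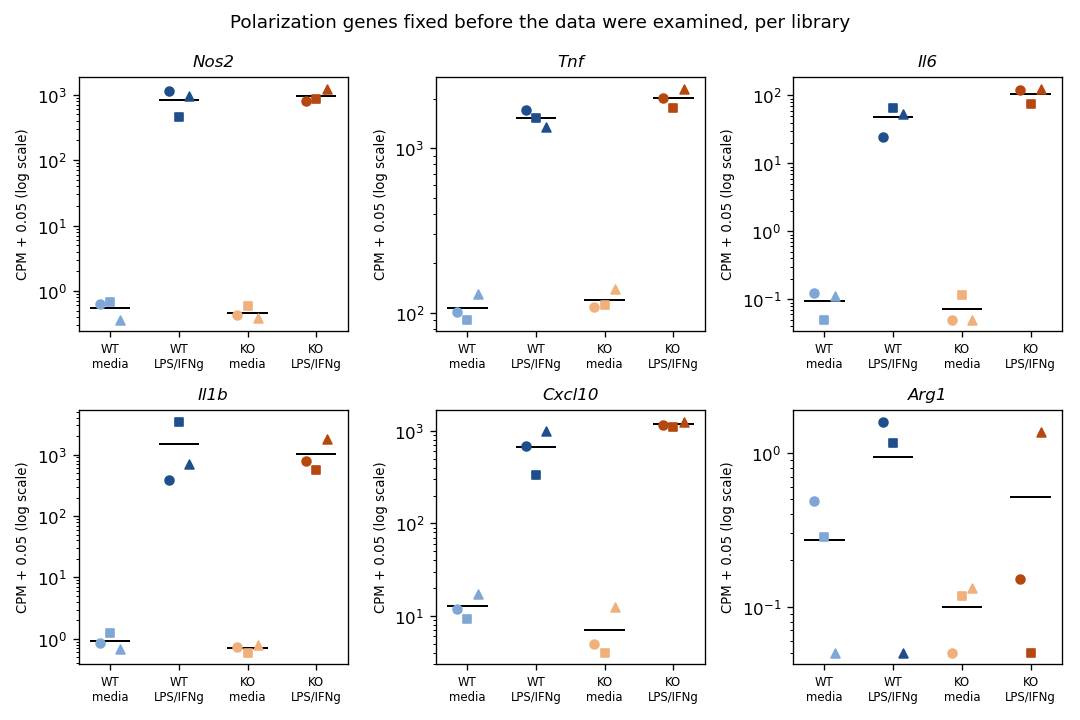
CPM plus 0.05 on a log axis for Nos2, Tnf, Il6, Il1b, Cxcl10 and Arg1 in each of the 12 libraries (circle, square and triangle for WT 1, 2 and 3 or KO 1A, 1B and 2), grouped by genotype and condition, with a line at the group mean. Nos2 goes from 0.506 to 839 CPM in WT clones and from 0.415 to 962 CPM in KO clones, while the Arg1 mean is at most 0.889 CPM in any group.

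By group, the KO response had 29 of 29 NF-kB targets higher (adjusted p = 0.012 with an estimated correlation) and 25 of 25 IFN-gamma and GBP/IRG genes (adjusted p = 0.00086 with an estimated correlation). It had 14 of 16 chemokines higher and 1 lower (adjusted p = 0.012 with an estimated correlation), and 18 of 24 feedback inhibitors higher and 2 lower (adjusted p = 0.031 with an estimated correlation). Type I interferon genes were higher in 34 of 34 cases (adjusted p = 0.34 with an estimated correlation) and MHC class I genes in 17 of 18 (adjusted p = 0.071 with an estimated correlation, and 0.028 with clone as a block). Stress response genes rose in 17 of 21 cases, with Herpud1 at 2.23 ± 0.12 and Asns at 1.53 ± 0.13 (camera adjusted p = 3.3e-09, and adjusted p = 0.14 with an estimated correlation). Proliferation genes fell in 25 of 30 cases (adjusted p = 0.51 with an estimated correlation) and histone genes in 13 of 13 (adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone, chemokines had 15 higher, feedback inhibitors 19 higher and proliferation genes 28 lower, and the other counts stayed.

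Glycolysis genes were higher in 17 of 23 cases and lower in 1 (camera 0.00067, and adjusted p = 0.34 with an estimated correlation). AP-1 genes were higher in 11 of 16 (0.00077, and adjusted p = 0.34 with an estimated correlation). Heat shock chaperones were higher in 9 of 11 (0.0054, and adjusted p = 0.41 with an estimated correlation) and phagocytosis genes in 14 of 24 with 1 lower (adjusted p = 0.51 with an estimated correlation). Matrix and adhesion genes were higher in 13 of 23 cases and lower in 6 (adjusted p = 0.51 with an estimated correlation). Signalling components had 17 of 33 higher and 6 lower (camera adjusted p = 0.020, and 0.057 with clone as a block; adjusted p = 0.51 with an estimated correlation). NRF2 targets had 8 of 15 higher and 1 lower (0.070, and 0.014 with clone as a block, lost at adjusted p = 0.48 with an estimated correlation) and cholesterol genes 10 of 22 higher and 2 lower (0.054). Not called were MHC class II (2 of 5 higher), alternative activation (3 of 8 higher), macrophage identity (14 higher and 7 lower of 23), osteoclast genes (4 and 2 of 15) and p53 targets (8 and 6 of 19). Nor were LXR targets (3 and 2 of 15), oxidative phosphorylation (8 and 1 of 27), lysosome genes (7 and 5 of 25) and mitochondrially encoded genes (0 of 7). Adjusted over the list alone, glycolysis genes had 18 higher, matrix genes 14 higher, signalling components 7 lower and osteoclast genes 1 lower, and the other counts stayed. Library totals turned the medians of the osteoclast, p53, LXR, oxidative phosphorylation and lysosome lists below 0, with 3 and 3, 6 and 9, 2 and 5, 1 and 10, and 5 and 10 genes higher and lower. They gave 12 and 10 for signalling components, 13 and 2 for glycolysis, 5 and 0 for chaperones, 5 and 4 for cholesterol and 10 and 8 for macrophage identity.

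In medium, 4 Y-linked genes stood near background in KO clones. Ddx3y, a Y-linked RNA helicase gene, stood at 140 ± 6.64 CPM in WT and 1.72 ± 0.939 in KO clones (-6.37 ± 0.36, adjusted p = 3.2e-05). Kdm5d (-6.39 ± 0.43), Uty (-6.21 ± 0.51) and Eif2s3y (-6.13 ± 0.43) fell likewise. Gm47283, which the annotation also places on the Y chromosome, was not called (-0.76 ± 0.24, adjusted p = 0.16). The X-linked Kdm6a, which encodes a histone demethylase, fell from 51.3 ± 0.307 to 2.55 ± 1.30 CPM (-4.31 ± 0.43, adjusted p = 0.0013). The long noncoding gene Gdap10 fell from 13.5 ± 0.550 to 0.683 ± 0.565 CPM (-4.23 ± 0.52, adjusted p = 0.0040). Gdap10 lies on mm10 chromosome 12 at 32821872 to 32826904, on the plus strand inside the span of Nampt (32819545 to 32853349, plus strand) with no shared exon. Nampt, the gene of the rate-limiting enzyme of NAD salvage, was at 161 ± 58.4 and 184 ± 9.14 CPM (0.19 ± 0.20, adjusted p = 0.75).

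In all, 148 genes were called for KO against WT in medium, 43 higher and 105 lower, with 8 and 48 of them past a 4-fold change. Higher in KO clones were Ranbp3l (1.28 ± 1.96 to 160 ± 111 CPM, 6.87 ± 1.08), the semaphorin gene Sema6d (5.74 ± 0.92), the guanylate cyclase gene Gucy2g (4.65 ± 0.56), Gpr161 (3.54 ± 0.67) and Zfp345 (3.49 ± 0.51). So were the inositol transporter gene Slc5a3 (1.98 ± 0.31), Tmem38b (1.84 ± 0.17, adjusted p = 0.00046), the stress-induced mTOR inhibitor gene Ddit4 (1.81 ± 0.29) and Ets2 (1.32 ± 0.25). Gcnt1, a glycosyltransferase gene, fell by 5.20 ± 0.58 on the log2 scale and Prune2 by 4.10 ± 0.31.

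Of 24 genes of the phagocytosis and Fc receptor list 4 were lower in KO clones in medium and 20 were not called (7 lower and 1 higher adjusted over the list alone). The 4 were the integrin gene Itgam (-1.75 ± 0.26), the Fc receptor chain gene Fcer1g (-1.73 ± 0.32), the scavenger receptor gene Msr1 (-2.74 ± 0.50) and the complement receptor gene C3ar1 (-2.55 ± 0.46). Camera gave an adjusted p of 4.3e-07, lost with fry (0.24) and at adjusted p = 0.72 with an estimated correlation. Itgam, Fcer1g and Msr1 were also the 3 of 23 macrophage identity genes that fell (5 lower and 1 higher adjusted over the list alone; camera 7.2e-06, and adjusted p = 0.72 with an estimated correlation). Integrins went both ways: Itga4 (1.47 ± 0.21, 890 ± 257 to 2460 ± 114 CPM) and Itgal (3.99 ± 0.59) rose and Itgb7 fell (-3.49 ± 0.45). These were the 3 called genes among 23 of matrix and adhesion (3 higher and 11 lower adjusted over the list alone; camera 0.0041 downward, and adjusted p = 0.72 with an estimated correlation). Also lower were the lipase gene Lpl (-2.20 ± 0.44), the chemokine gene Ccl9 (-2.35 ± 0.43) and Cdkn1a (-0.49 ± 0.09, lost at adjusted p = 0.072 under library totals), a cell cycle inhibitor and p53 target, while Sesn1, another p53 target, rose (1.26 ± 0.23).

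Camera called 9 further lists lower in medium with 0 members called by edgeR over all genes, and each call was lost with an estimated correlation. These were cholesterol synthesis (adjusted p = 2.6e-05, 2 genes lower adjusted over the list alone, and adjusted p = 0.72 with an estimated correlation) and lysosome (0.00018, 1 gene, and adjusted p = 0.73 with an estimated correlation). They also held osteoclast genes (0.0041, 8 lower and 2 higher, and adjusted p = 0.72 with an estimated correlation) and alternative activation (0.0064, 3 genes, and adjusted p = 0.73 with an estimated correlation). NRF2 targets (0.0064, 0 genes, and adjusted p = 0.73 with an estimated correlation) and AP-1 genes (0.040, 4 genes, and adjusted p = 0.73 with an estimated correlation) followed. The last were MHC class I (0.046, 0 genes, and adjusted p = 0.83 with an estimated correlation), stress response genes (0.046, 0 genes, and adjusted p = 0.75 with an estimated correlation) and type I interferon genes (0.048, 0 genes, and adjusted p = 0.86 with an estimated correlation). The interferon list turned upward without WT clone 3 (7.8e-05), and 7 of the 12 list calls in medium were lost or turned without at least 1 clone. Median, mean and test differed in sign for the NF-kB and glycolysis lists, neither of them called in medium.

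The count in medium depended on the clones and the test. It was 14 without KO 1A, 24 without KO 1B, 419 without WT 3 and 16 with KO 1A and 1B summed. Of the 28 called genes named above 20 lost their call without KO 1A, 17 without KO 1B, 4 without KO 2, 7, 7 and 1 without WT 1, 2 and 3 and 19 with KO 1A and 1B summed. With the 2 summed, the calls kept were those of Ddx3y, Kdm5d, Uty, Eif2s3y, Kdm6a, Gdap10, Prune2, Gucy2g and Tmem38b. Among those lost were Itgam (adjusted p = 0.12), Fcer1g (0.26), Msr1 (0.21), C3ar1 (0.23), Itga4 (0.10), Itgal (0.080), Itgb7 (0.074), Lpl (0.30), Ccl9 (0.19), Cdkn1a (0.26) and Sesn1 (0.20). DESeq2 called 622, edgeR on the 6 libraries alone 89, voom with spread by genotype 247 and a test against a fold of 1.5 called 45.

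**Figure D3:**
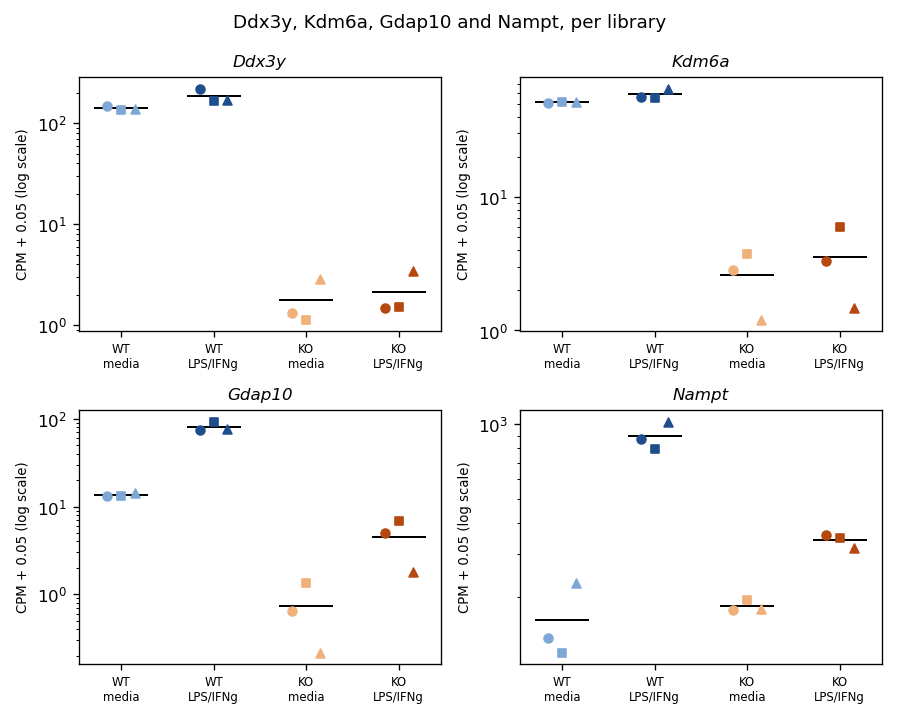
CPM plus 0.05 on a log axis for Ddx3y, Kdm6a, Gdap10 and Nampt in each of the 12 libraries (circle, square and triangle for WT 1, 2 and 3 or KO 1A, 1B and 2), grouped by genotype and condition, with a line at the group mean. Ddx3y, Kdm6a and Gdap10 are lower in every KO library than in every WT library of the same condition, and Nampt means are 897 CPM in stimulated WT and 340 CPM in stimulated KO clones.

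Under LPS/IFN-gamma, single inflammatory genes differed between KO and WT clones. Nfkbiz, a nuclear co-regulator of NF-kB, stood at 161 ± 38.9 CPM in WT and 719 ± 81.3 in KO clones (2.16 ± 0.21, adjusted p = 0.00088). The chemokine genes Ccl22 (138 ± 58.8 to 377 ± 22.3 CPM, 1.45 ± 0.28) and Ccl17 (3.49 ± 0.64) were higher. So were the cytokine gene Lif (1.96 ± 0.41) and the protease gene Mmp9 (3.26 ± 2.27 to 37.4 ± 0.680 CPM, 3.52 ± 0.56). Nampt was lower, at 897 ± 116 CPM in WT and 340 ± 20.8 in KO clones (-1.40 ± 0.21, adjusted p = 0.0056). Gdap10 was lower too, at 81.2 ± 10.0 and 4.50 ± 2.57 CPM (-4.16 ± 0.45, adjusted p = 0.0013). The interleukin-1 receptor antagonist gene Il1rn (-4.30 ± 1.03), the mannose receptor gene Mrc1 (-3.01 ± 0.52) and the fusion gene Dcstamp (-3.19 ± 0.59) were also lower.

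In this condition 567 genes were called, 138 higher and 429 lower, with 17 and 106 past a 4-fold change. Of the calls in medium and under stimulation, 18 were higher in both, 76 lower in both and 1, Cdkn1a, opposite (0.48 ± 0.09 under stimulation), where independent lists would share 0.485 and 3.68. The same 6 clones gave both sets of libraries, so the 2 comparisons are not independent. The overlap of 94 became 11 without KO 1A, 18 without KO 1B, 241 without WT 3, 13 with KO 1A and 1B summed and 332 with DESeq2. The shared genes included Ddx3y (-6.47 ± 0.36), Kdm5d (-6.47 ± 0.46), Uty (-6.43 ± 0.53), Eif2s3y (-6.19 ± 0.44), Kdm6a (-4.04 ± 0.43), Prune2 (-4.58 ± 0.36), Gcnt1 (-4.52 ± 0.60), Itgb7 (-2.90 ± 0.43) and Lpl (-2.01 ± 0.43). Higher in both were Ddit4 (2.64 ± 0.31), Gpr161 (2.68 ± 0.65), Ets2 (1.30 ± 0.25) and Tmem38b (1.12 ± 0.17). Sema6d had 609 counts in KO and 3 in WT clones, a 218-fold ratio with an interval of 74.4 to 1062. Also lower were the secreted factor gene Angptl2 (-5.62 ± 1.16), Xirp1 (-4.88 ± 0.81) and the selectin ligand gene Selplg (-2.86 ± 0.50), and the transcriptional regulator genes Id3 (2.26 ± 0.29) and Fosb (2.53 ± 0.44) rose.

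By camera and fry, stress response genes were higher in stimulated KO clones: 3 of 21 were called over all genes and 18 were not, and 12 were higher adjusted over the list alone. Herpud1, a component of endoplasmic reticulum protein disposal, went from 142 ± 14.5 to 310 ± 24.4 CPM (1.13 ± 0.12, adjusted p = 0.0012). The chaperone gene Dnajb9 rose by 0.81 ± 0.19 and the asparagine synthetase gene Asns by 0.66 ± 0.13. Camera gave 2.6e-09, fry 0.041, and adjusted p = 0.54 with an estimated correlation. Of 29 NF-kB targets 3 rose, Nfkbiz, Lif and Nfkbia (0.43 ± 0.10), with 4 higher adjusted over the list alone (camera 0.0014, and adjusted p = 0.59 with an estimated correlation). Heat shock chaperones had 0 of 11 called (4 higher adjusted over the list alone; camera 0.0024, and adjusted p = 0.59 with an estimated correlation). In the p53 list Cdkn1a and Zmat3 (0.86 ± 0.19) were higher and Mdm2 (-0.91 ± 0.23) and Plk2 (-4.04 ± 0.89) lower among 19 (3 higher and 2 lower adjusted over the list alone). Camera gave that list 0.040 upward, and adjusted p = 0.59 with an estimated correlation.

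Lower lists under stimulation were macrophage identity, with Trem2 (-2.01 ± 0.46) and Laptm5 (-0.68 ± 0.14) called of 23 (11 lower and 1 higher adjusted over the list alone; camera 0.00012, and adjusted p = 0.59 with an estimated correlation). Among lysosome genes Tfeb was called (-1.07 ± 0.21) of 25 (7 lower adjusted over the list alone; 0.00013, and adjusted p = 0.59 with an estimated correlation). Mrc1 was the called gene of 24 in the phagocytosis list (4 lower adjusted over the list alone; 0.0022, and adjusted p = 0.59 with an estimated correlation). It was also the called gene of 8 in the alternative activation list (1 lower adjusted over the list alone; 0.019, and adjusted p = 0.59 with an estimated correlation). Matrix and adhesion genes had 4 of 23 lower and 1 higher (8 and 1 adjusted over the list alone; 0.020, and adjusted p = 0.59 with an estimated correlation). Lists not called included the IFN-gamma and GBP/IRG genes, of which Iigp1 (2280 ± 353 to 1295 ± 51.7 CPM, -0.82 ± 0.16) and Il18bp (-1.72 ± 0.42) were lower among 25. Median, mean and test differed in sign for the type I interferon, MHC class I and LXR lists, none of them called. The cholesterol exporter gene Abca1 rose (2.28 ± 0.54), and the LXR list that holds it was not called. Of the 9 list calls here, those for alternative activation, p53 targets and matrix genes were lost without at least 1 clone.

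The count of 567 became 48 without KO 1A, 69 without KO 1B, 287 without KO 2, 972 without WT 3 and 73 with KO 1A and 1B summed. Of the 46 called genes named for stimulated cells 34 lost their call without KO 1A, 32 without KO 1B, 20 without KO 2, 14, 12 and 5 without WT 1, 2 and 3 and 32 with KO 1A and 1B summed. With the 2 summed, Nampt (adjusted p = 0.072), Ccl22 (0.11), Ccl17 (0.15), Lif (0.065), Mmp9 (0.085), Mrc1 (0.11), Il1rn (0.25) and Dcstamp (0.15) lost theirs, and Nfkbiz (0.018), Herpud1 (0.018) and Gdap10 (0.023) kept theirs. DESeq2 called 1177 genes, edgeR on the 6 libraries alone 96 and a test against a fold of 1.5 called 78.

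**Figure D4:**
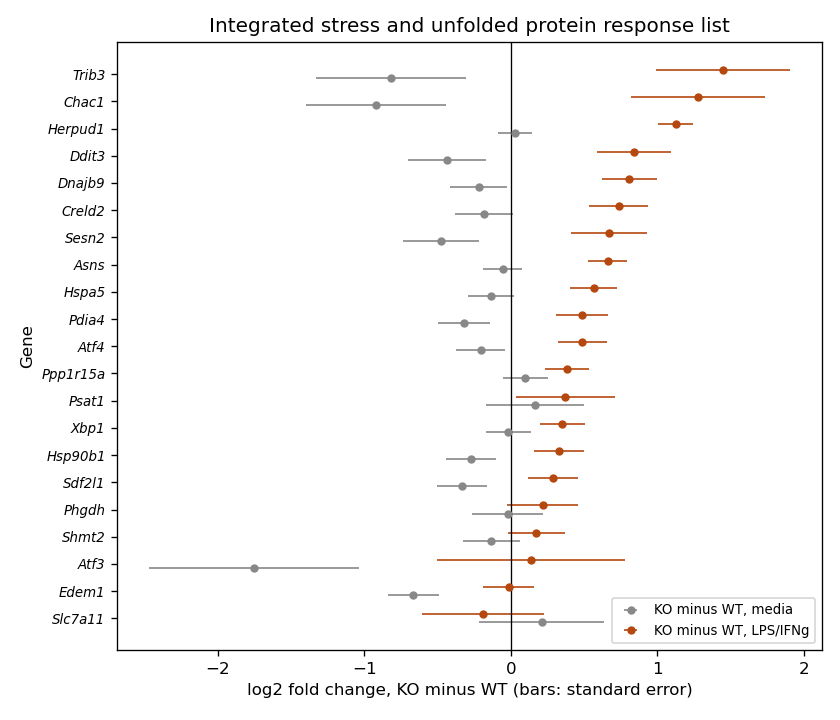
Log2 fold change of KO against WT for each of the 21 measured genes of the stress response list, with bars of 1 standard error, in medium (gray) and under LPS/IFN-gamma (brown). Herpud1 is at 1.13 under stimulation, and the list median goes from -0.20 in medium to 0.49 under stimulation.

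The test of whether the response itself differed between genotypes called 0 genes with edgeR, with a smallest adjusted p of 0.12 and 611 genes at an unadjusted p below 0.05. DESeq2 called 20 and voom 0, and edgeR with clone as a block called 40, 20 with a higher and 20 with a lower KO response. Without WT 2 the count was 1 and without WT 3 it was 4, against 0 without each of the other clones. Genes at that smallest adjusted p included Herpud1 (1.10 ± 0.17), Cdkn1a (0.97 ± 0.13) and Inpp1 (-1.49 ± 0.22), and with the block their adjusted p were 0.017, 0.025 and 0.040. Nampt had a log2 response of 2.47 in WT and 0.89 in KO clones (difference -1.59 ± 0.29, adjusted p = 0.43, and 0.017 with clone as a block).

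By camera, stress response genes showed a larger KO than WT response as a group: their median difference was 0.70, with 0 of 21 called over all genes and 14 higher adjusted over the list alone. Camera gave 7.5e-26, with adjusted p = 0.035 with an estimated correlation and fry at 0.049, and with the clone block both were lost (adjusted p = 0.19 with an estimated correlation and fry at 0.072). Cholesterol synthesis genes had 0 of 22 called and 6 higher adjusted over the list alone (camera 1.1e-14, and adjusted p = 0.19 with an estimated correlation). NRF2 targets were not called (0.050). They were called with clone as a block (0.00053), a call lost at adjusted p = 0.55 with an estimated correlation and with fry (0.32). Camera also called 8 further lists with 0 members called over all genes. Upward were p53 targets (0.00031, and adjusted p = 0.063 with an estimated correlation) and chemokines (0.0018, and adjusted p = 0.30 with an estimated correlation). Type I interferon genes (0.0016), MHC class I (0.0038), AP-1 (0.012), NF-kB (0.020, and 0.18 with clone as a block) and phagocytosis genes (0.034) were upward and histones (0.047) downward, each at adjusted p = 0.91 with an estimated correlation. An upward interaction need not mean a higher stimulated level. KO minus WT medians in medium and under stimulation were -1.72 and -1.05 for phagocytosis, -0.51 and -0.25 for AP-1 and -1.03 and 0.03 for type I interferon genes. The other upward lists had medians above 0 under stimulation, that of MHC class I near 0 at 0.016. Adjusted over the list alone, 4 AP-1 genes, 1 NF-kB gene and 1 p53 target were higher. Without WT 1 the number of lists called was 6 instead of 10. Median, mean and test differed in sign for the IFN-gamma and GBP/IRG, feedback inhibitor, macrophage identity, matrix and dendritic lists, none of them called.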

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

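Of the tests of explanations here, the 1 for a larger response of all genes was written down before its result was seen, and the others (single clones, members moving together, splits of the clones) were chosen after. Each result below is a difference between the KO and the WT response to LPS/IFN-gamma, by a test of that difference.

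With clone as a block, edgeR called 40 genes for the interaction, against 0 without it. Among those with a higher KO response were the chemokine genes Ccl4 (2.68 ± 0.31) and Ccl3 (1.59 ± 0.17), the heme oxygenase gene Hmox1 (1.82 ± 0.20), Cdk2ap2 (1.73 ± 0.22) and Ankrd33b (1.66 ± 0.25). A lower KO response was called for the NF-kB adaptor gene Tifa (-1.62 ± 0.18), Nampt (-1.64 ± 0.16), Stx3 (-1.71 ± 0.17), Inpp1 (-1.48 ± 0.22) and the nucleic acid sensor gene Tlr13 (-2.28 ± 0.33). Tifa had a log2 response of 1.60 in WT and -0.02 in KO clones. Without the block, edgeR gave Tifa, Hmox1, Ccl3 and Tlr13 an adjusted p of 0.999984. The block fit takes KO 1A and 1B as separate clones and was not run with the 2 summed, so the calls were not checked for that. In simulated counts 11.9% of the interaction calls with the block were false. In the 10 splits of the 6 clones into groups of 3 the real one gave 40 genes and the highest other 0, and 10 splits cannot give a share below 0.05. The other splits mix KO and WT clones, so a real difference would widen their spread. Without the block all 10 gave 0.

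By camera without the block, the interaction was called upward for cholesterol synthesis (adjusted p = 1.1e-14, and 0.19 with an estimated correlation), p53 targets (0.00031, and 0.063), type I interferon genes (0.0016, and 0.91), chemokines (0.0018, and 0.30) and MHC class I genes (0.0038, and 0.91). The same test gave 0.012 for AP-1 genes, 0.020 for NF-kB targets and 0.034 for phagocytosis genes, upward, and 0.047 for histone genes, downward, each at 0.91 with an estimated correlation. These upward calls are of a more positive response, not of a higher stimulated level. The phagocytosis and AP-1 lists had KO minus WT medians below 0 under stimulation (-1.05 and -0.25), and the other upward lists had medians above 0. Those of the MHC class I and type I interferon lists were near 0 (0.016 and 0.026), and neither list was called for KO against WT under stimulation. With clone as a block the NF-kB call was lost (0.18). Without WT 1 the calls for NF-kB targets (0.39), p53 targets (0.12), AP-1 genes (0.078) and histones (0.10) were lost. Without WT 2 those for histones (0.88) and phagocytosis (0.40) were lost, and without WT 3 those for type I interferon (0.59) and MHC class I genes (0.057). Without KO 1A histones (0.21) and phagocytosis (0.064), without KO 1B phagocytosis (0.068) and without KO 2 NF-kB targets (0.061) and histones (0.093) lost theirs.

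The stress response list was called upward at a camera adjusted p of 7.5e-26. Its median interaction was 0.70, against 0.34 in the highest other of 10 splits. The splits are too few for a share below 0.05, and all but the real one mix KO and WT clones. A single clone as the source of the list result is argued against by the lowest median with 1 clone left out, 0.62 without WT 2. As KO 1A and 1B may be 1 clone, both were also left out (0.79) and summed (0.67), which left adjusted p = 0.495 and 0.097 with an estimated correlation. To test a larger response of all genes in KO clones, a common slope of 1.05 over 7218 genes was taken out. The list median was then 0.67, so such a response accounted for little of the difference in these clones. The SE of that median, 0.18, takes the 21 list genes as independent and leaves out the spread between clones. Members moving together between clones stay open: the adjusted p with an estimated correlation was 0.035 without and 0.19 with the clone block, and with 1 clone left out it was 0.078, 0.021 and 0.21 for WT 1, 2 and 3 and 0.13, 0.085 and 0.066 for KO 1A, 1B and 2. An effect of the deletion on this list therefore cannot be told apart from a difference between clones that moves these genes together. Further independent KO clones, or return of the segment, would test it.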

How the results depend on the processing

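The alternatives were fixed before the data were examined, except the voom fit with spread by genotype, which was chosen after. For the 193 gene results named, 3023 comparisons with alternatives were made: called genes kept their side of the threshold in 2280 and lost it in 333 and 0 turned direction, while genes not called stayed so in 379, passed in 26 and turned direction in 5. These were Eif2s3x in medium, near 0 at -0.03 and at 0.026 under library totals, 0.14 without WT 3 and 0.01 without KO 2 (-0.13 without WT 1), and Ddx3x in medium, at -0.06 and at 0.00042 under library totals and 0.0223 without KO 2 (-0.15 without WT 2). The response counts stayed within 1.5 times under RLE factors, library totals, DESeq2, voom, other filters, thinning and the block, and without each clone lay between 4741 and 5075 in WT and between 4587 and 5057 in KO clones. A test against a fold of 1.5 called 2462 and 3198 genes, fewer by construction.

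KO against WT in medium gave 622 genes with DESeq2, 247 with voom and spread by genotype, 89 with the 6 libraries alone, 45 against a fold of 1.5, 16 with KO 1A and 1B summed, and 14 to 419 with 1 clone left out (without KO 1A and without WT 3). Under LPS/IFN-gamma the counts were 1177 with DESeq2, 96, 78 and 73 for the 6 libraries, the fold of 1.5 and the summed clones, and 48 to 972 with 1 clone left out (the same clones). The overlap of 94 was 332 with DESeq2, 13 with summed clones and 11 to 241 with 1 clone left out. The interaction gave 20 genes with DESeq2 and 0 to 4 with 1 clone left out. The test against a fold of 1.5 is stricter by construction, and the causes of the other differences were not tested.

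List calls with an estimated correlation were 4 for each response, 0 for KO against WT in each condition and 1 for the interaction. Without the block, the correlation estimated was above the preset 0.01 for every list called. Fry called 23 lists for the KO response, 0 in medium, 1 under LPS/IFN-gamma and 1 for the interaction, and the interaction calls with 1 clone left out were 6 to 12 (without WT 1, and without WT 2 or KO 1B). The type I interferon list in medium turned upward without WT 3 (adjusted p = 7.8e-05), and its adjusted p without 1 clone ranged from 2.2e-08 to 0.091; the cause was not tested.

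With clone as a replicate block the counts were 7485 for the WT and 8082 for the KO response and 40 for the interaction. The block is given beside each gene call and camera call that it changed, and it changed no other gene or camera call of those named. Fry with the block is given for the stress list alone, where the interaction call was lost (0.072). No paired analysis was possible because WT and KO are different clones, for KO against WT in medium and under LPS/IFN-gamma. Depth limits genes near 0 counts, whose folds carry wide counting intervals.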

Other observations

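Some genes of NAD and itaconate metabolism, chosen after their values were seen and with no list or group test behind them, were called in both responses, in which 47.4% (WT) and 54.3% (KO) of all genes were called. Acod1, which makes itaconate, rose from 11.7 ± 6.51 to 8049 ± 2282 CPM in WT (9.43 ± 0.52) and from 5.05 ± 1.27 to 7331 ± 1824 CPM in KO clones (10.50 ± 0.55), by edgeR. The ADP-ribosyltransferase genes Parp14 (4.84 ± 0.52 in WT, 5.39 ± 0.53 in KO) and Parp9 (3.28 ± 0.34, 3.47 ± 0.34) rose, as did the NAD kinase gene Nadk (1.15 ± 0.13, 1.04 ± 0.13) and the NAD-consuming Bst1 (2.85 ± 0.62, 2.49 ± 0.62). Parp1 (-1.44 ± 0.16, -1.56 ± 0.16) and Nmnat3 (-1.24 ± 0.30, -1.51 ± 0.31) fell. None of these 7 genes was called for KO against WT in either condition. Under stimulation Ass1, an enzyme gene of arginine supply, was lower in KO clones (57.2 ± 50.1 and 7.23 ± 2.48 CPM, -2.98 ± 0.68, adjusted p = 0.038). That call was lost with KO 1A and 1B summed.

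Of the tests below, that of chromosome medians was written down before its result was seen, and all others were chosen after. The 4 counts by edgeR were each set beside the 10 splits of their 6 libraries, too few for a share below 0.05, and the real split stood alone at its size in each (1 of 10). Every other split put members of both real groups on each side. A real difference would widen the spread there and lower the calls, so their low counts decide nothing. The WT response gave 5796 genes and the highest other split 3, the KO response 6638 and 0, KO against WT in medium 148 and 5, and under LPS/IFN-gamma 567 and 24. The overlap was 94, with 2 in the highest other split. Other splits that parted all 3 pairs of a clone's libraries gave 0 genes in each response. A gained or lost whole autosome or X chromosome in the KO clones is argued against by the medians of these chromosomes, each with at least 50 tested genes, which lay at most 0.034 log2 from that of all genes. The Y chromosome, with 5 tested genes, had too few for this test and is taken up next.

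The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y stood near background in KO clones. Reads of Uty and Eif2s3y counted for their X-linked partners are argued against by Kdm6a and Eif2s3x, whose smallest distance below the fold change needed was 12 SE over both conditions (in medium Kdm6a at -4.31 ± 0.43 against 1.11 and Eif2s3x at -0.03 ± 0.15 against 3.44). For Ddx3y and Kdm5d the X-linked partners cannot decide this. Ddx3x was at -0.06 ± 0.20 against 0.24 in medium and at 0.22 ± 0.20 against 0.17 under stimulation, a distance below it of -0.229 SE. Kdm5c was 5.09 SE below the value needed in medium and 1.67 SE under stimulation. All libraries were counted into 1 table, in which WT clones held reads of both Y-linked genes. Such miscounting would thus have to act in KO libraries alone. Loss of the Y chromosome in clones regardless of genotype stays open. With 3 of 6 clones without these transcripts, 0.05 of the assignments would put all 3 in the KO group whatever the cause, so this share decides nothing, and KO 1A and 1B may share 1 event. Gm47283, the other tested gene that the annotation places on the Y chromosome, was at -0.76 ± 0.24 in medium by edgeR (adjusted p = 0.16). Whether its reads can also come from the X chromosome was not tested, so its level does not bear on Y loss. An effect of the deletion itself was not tested.

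Gdap10, inside the Nampt span, was lower in KO clones in both conditions, and Nampt under stimulation alone was called lower. Whether reads from Nampt introns were counted for Gdap10 stays open. The log2 ratio of Gdap10 to Nampt, KO minus WT, with 0.5 CPM added to each gene, was -3.92 ± 0.45 (SE) in medium and -2.79 ± 0.50 under stimulation. Gdap10 stood at 0.683 CPM in KO clones in medium, so the ratio there depends on the added value. A deletion of this part of Nampt would lower the ratio for intron reads as well, so the ratio cannot decide. Within WT clones the log2 ratio was -3.48 in medium and -3.46 under stimulation, so Gdap10 rose with Nampt there. A local change around the locus stays open. Of 8 other genes within 1 Mb, 2 were called lower under stimulation, Pik3cg (-0.58 ± 0.14, adjusted p = 0.044) and Ccdc71l (-0.92 ± 0.23, adjusted p = 0.0498). Both calls were lost with KO 1A and 1B summed. Of the windows around other genes 16.8% held as many. The windows were not matched for their number of genes, so this share cannot decide. That the deleted segment lies at this locus is a hypothesis that the labels leave open and that sequencing the clones' DNA would test.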
